A study of Mus musculus with 16 samples.

How the data were processed

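Polyadenylated RNA from the brain cortex of 16 mice aged 5 months was sequenced, with 1 library per animal and 4 animals in each of 4 genotypes. The genotypes were wild-type C57BL/6J mice, Dp16 mice, 5xFAD mice, and mice carrying both (5xFAD-Dp16). Dp16 mice carry a duplication of the segment of mouse chromosome 16 that corresponds to most of human chromosome 21. 5xFAD mice carry human transgenes with familial Alzheimer mutations, driven by the Thy1 promoter. Per the labels' protocols, RNA was extracted with TRIzol, its quality and amount were read on a TapeStation and a Qubit, strand-specific libraries were made with a Tecan mRNA kit, and paired reads were taken on a NovaSeq instrument.

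The count table holds raw read counts per gene, deposited by the authors as whole numbers for 55385 genes, with no normalization. A second table holds RPKM values deposited by the authors, that is, read counts scaled by gene length and by the library total. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.1.0, HTSeq 0.6.1, SAMtools 1.5 and bcl2fastq were used with genome build GRCm38. The notes give no role for each tool, no strand setting for the counting and no filter. The RPKM table served only to check the counts and to give gene lengths: 100.0% of non-zero values satisfied the relation between count, length, column total and RPKM within 0.1%.

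The counts were made on the Gencode vM24 annotation. Coordinates came from Gencode M21, which uses the same build, joined by gene identifier. Of the genes, 55144 were matched, each on the same chromosome in both, and 241 were not. The triplicated region was taken as chromosome 16 from 75540514 to 97962622, from the start of Lipi to the end of Zbtb21, a length of 22.4 Mb. It holds 384 genes of the count table, of which 147 are protein-coding.

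Library totals ran from 12483286 to 20385010 counted reads. Genes were kept by edgeR's filterByExpr, which left 17019 genes, and libraries were scaled by TMM factors. A single model with a mean for each genotype and an additive sex term was fitted to the 16 libraries with edgeR 4.0.16 in R 4.3.3, using robust quasi-likelihood dispersions. The common biological coefficient of variation was 0.266 and the median prior degrees of freedom were 5.77. Each comparison was tested with edgeR's two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p-values of single genes below come from this test unless another is named. They measure the spread between animals.

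The comparisons were Dp16 against wild-type, 5xFAD against wild-type, 5xFAD-Dp16 against 5xFAD, against Dp16 and against wild-type, and the interaction. The interaction is the Dp16 effect on the 5xFAD background minus the Dp16 effect without it. The sex difference in 5xFAD minus that in wild-type and Dp16 was tested in a separate model. The groups, comparisons, tests, gene lists, rule for named genes and the first set of alternatives were fixed before the data were examined.

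Of 35 gene lists fixed in advance, 34 were tested; the histone list had 0 measured members. The lists cover the triplicated region, the rest of chromosome 16, orthologs of human chromosome 21 on mouse chromosomes 10 and 17, microglial states, myeloid cells, lymphocytes, macrophages, astrocytes, oligodendrocyte stages, excitatory and inhibitory neurons, vessels, choroid plexus, blood and neighbouring brain regions. They also cover immediate early genes, interferon-stimulated genes outside chromosome 16, complement, antigen presentation, lysosome, cholesterol synthesis, synaptic proteins, the unfolded protein response, heat shock, oxidative stress, oxidative phosphorylation, the mitochondrial genome, ribosomal proteins and clustered protocadherins. Each list was tested two-sided with camera in limma 3.58.1, which compares its genes with all others, at a preset correlation of 0.01. Camera was run again with the correlation estimated for each list, and fry tested whether a list's genes moved one way on balance. Adjusted p-values of lists are Benjamini-Hochberg over the lists of a comparison. Counts adjusted over the list alone apply the adjustment to the members of that list only. A list score is the mean over the members of the library's log2 CPM (prior count 2) minus the wild-type mean, compared between groups of 4 by a two-sided exact permutation test with 70 assignments, whose smallest possible p is 0.0286.

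Named genes included App, Thy1 and the sex-linked Xist, Ddx3y, Uty, Kdm5d and Eif2s3y as checks of the labels. To these were added up to 10 of the most raised and 10 of the most lowered genes past the threshold with a mean log2 CPM of at least 0, an official symbol and groups that do not overlap, up to 4 members per list with the smallest adjusted p, and 13 genes of the triplicated region picked by function. Any other gene was chosen after its values were seen, and the text says so where it is named. Values per group are CPM, the counts scaled to a common library total, with the SD between animals. Some of the genes examined are not reported here, and the test for outlying libraries covers reported genes only.

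Alternatives fixed in advance were median-of-ratios (RLE) factors, DESeq2 1.42.0, no filter on low counts, a filter of CPM 1 in at least 4 libraries, no sex term, separate means per sex with the contrast among males, only the 2 groups compared in the model, the sample number as a block, the other list tests, and leaving out each library in turn. Chosen after the data were seen were leaving out wild-type replicate 2 and 5xFAD replicate 3 together, removing each library's trend of expression with gene length by offsets, that removal with the contrast among males, limma voom with a weight per library, and the lymphocyte list without Thy1. Where a model of only the 2 groups compared held 5xFAD-Dp16, whose animals were all males, the sex term came from the other group alone. The contrast was then with the males of that group, as in the contrast among males. The model was tested on simulated data with 200 changed genes. Without a length trend between libraries, at a 1.5-fold change it called 20.9% of them for 5xFAD against wild-type and 7.5% for Dp16 against wild-type, and at a 4-fold change 86.4% and 89.4%. With the libraries' length trends simulated and not removed, it called 1.5% at 1.5-fold and 81.8% at 4-fold for 5xFAD against wild-type.

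Where a group had no read of a gene, the floor was 3 counts over the pooled reads of that group. Floors cover counting error only. Reads were not collapsed by molecular identifiers. Human transgene transcripts were not analysed here, since the table is of mouse genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.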

Results

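Gene transcript levels were measured in cortex from 16 mice aged 5 months, 4 of each genotype. Wild-type, Dp16 and 5xFAD animals were 2 males and 2 females each, and the 4 animals with 5xFAD and Dp16 together (5xFAD-Dp16) were males. The wild-type libraries held 17063105, 12483286, 16353970 and 18556592 counted reads, and the Dp16 libraries 14181035, 17480827, 19718542 and 20385010. The 5xFAD libraries held 15000753, 17537999, 16872707 and 18203897 reads, and the 5xFAD-Dp16 libraries 20061944, 17571750, 18623283 and 17614561. Between 7.71 and 10.99% of reads came from the mitochondrial genome, with mt-Co1 the most abundant gene in the libraries. Xist and the Y-linked genes matched the labelled sex of each animal.

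Thy1, whose promoter drives the 5xFAD transgenes, stood at 886 CPM ± 41.5 (SD, n = 4) in wild-type and 863 ± 48.5 in Dp16, against 1640.0 ± 200.2 in 5xFAD and 1647 ± 138 in 5xFAD-Dp16. Counts per gene cannot show whether these reads came from the mouse gene or from any Thy1 sequence in the transgenes. The mouse gene App, present in an extra copy in Dp16, stood at 1155 ± 273 CPM in wild-type and 1614 ± 205 in Dp16, and at 837 ± 156 in 5xFAD and 1748 ± 225 in 5xFAD-Dp16. Wild-type replicate 2 and 5xFAD replicate 3 had median correlations with the other libraries of 0.939 and 0.938, against 0.953 to 0.972 for the rest. At equal depth, wild-type replicates 1, 2 and 3 had 18839, 18331 and 19056 detected genes and replicate 4 had 20288. The libraries of the other genotypes had 20083 to 21198, so comparisons with wild-type rest on a group that stands apart in this measure. The libraries also differed in how expression followed gene length. Spearman's rho between a library's deviation from the mean and gene length, across genes, ran from -0.462 in 5xFAD replicate 3 to 0.451 in 5xFAD-Dp16 replicate 1, and was above 0 in the 4 5xFAD-Dp16 libraries.

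Dp16 against wild-type asks what the extra segment does in cortex without amyloid transgenes. Genes of the triplicated region stood higher in Dp16 by a median of 0.55 on the log2 scale, or 1.46-fold, close to the 1.5-fold expected from 3 copies in place of 2. Of the 105 region genes tested, 94 were positive, against 50.1% of other genes, and the 415 genes on the rest of chromosome 16 had a median of 0.005. Jam2, a junctional adhesion molecule, rose from 58.3 ± 3.85 to 100.9 ± 11.2 CPM (SD, n = 4), and Morc3, a nuclear matrix ATPase, rose from 21.9 ± 3.50 to 38.4 ± 2.11 CPM. The only gene past the threshold outside the region was nonagouti (symbol a), the coat-colour signalling protein. Nonagouti had 0 reads in the 4 wild-type libraries and 41 to 98 in each Dp16 library, a mean of 3.12 ± 1.28 CPM that is at least 66-fold above the floor of 0.0466 CPM set by 3 counts over the pooled wild-type reads.

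Jam2 (ENSMUSG00000053062.16, chromosome 16, 84774123 to 84825928, GRCm38) changed by 0.79 on the log2 scale (SE 0.12, adjusted p = 0.0322). Morc3 (ENSMUSG00000039456.10, chromosome 16, 93832121 to 93876073) changed by 0.81 (SE 0.13, adjusted p = 0.0322), and nonagouti (ENSMUSG00000027596.10, chromosome 2, 154791402 to 155051012) had an adjusted p of 0.0187. Over all genes these 3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 2 lie in the region, while 46 region genes rose when adjusted over the list alone. Camera gave the region an adjusted p of 2.58e-56, and the adjusted p was 4.13e-09 with an estimated correlation. The region score was 0.60 ± 0.029 in Dp16 against 0 ± 0.045 in wild-type (SD, n = 4, two-sided exact permutation p = 0.0286). Over the 92 region genes at 1 CPM or more the median was 0.54, also 1.46-fold.

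Among region genes picked by function, Dyrk1a, a dual-specificity kinase (ENSMUSG00000022897.15, chromosome 16, 94570010 to 94695517), stood at 65.1 ± 7.35 CPM in wild-type and 99.6 ± 4.00 in Dp16, a log2 change of 0.61 (SE 0.11, adjusted p = 0.107). The interferon receptor subunits Ifnar1, Ifnar2 and Ifngr2 had log2 changes of 0.77, 0.63 and 0.62, with adjusted p of 0.001, 0.00596 and 0.00117 over the list alone. The interleukin receptor subunit Il10rb, the calcineurin regulator Rcan1 and the superoxide dismutase Sod1 changed by 0.64, 0.49 and 0.53, with adjusted p of 0.0362, 0.0019 and 0.00663 over the list alone. The amyloid precursor gene App (ENSMUSG00000022892.11, chromosome 16, 84949685 to 85173766) had a log2 difference of 0.48 (SE 0.18, 1.40-fold, adjusted p = 1). Usp16, Olig1, Olig2 and Mx2 had values of 0.34, 0.41, 0.05 and 0.17, of which Olig2 turned to -0.015 once the length trend was removed, Usp16 to -0.037 with that removal and the contrast among males, and Mx2 to as low as -0.104 without a single library, and Mx1 was not tested because its counts were too low.

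**Figure D1:**
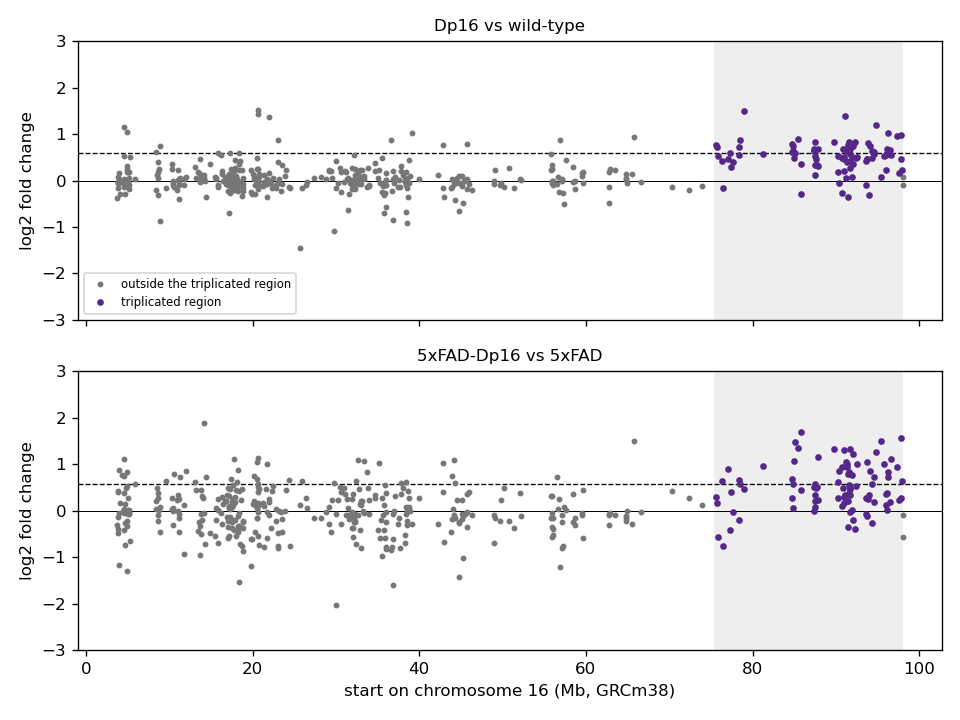
Log2 fold change of tested genes on chromosome 16 (vertical axis, -3 to 3) against their start in Mb on GRCm38 (horizontal axis), for Dp16 against wild-type and for 5xFAD-Dp16 against 5xFAD. Genes with a mean log2 CPM below 0 and genes beyond the axis are not drawn. Purple points are genes of the shaded triplicated region, grey points the other genes, and the dashed line marks a 1.5-fold change. Purple points gather around the dashed line in both panels, with medians of 0.54 and 0.48 over the 92 region genes at 1 CPM or more, while grey points centre on 0.

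Outside the region, 4 lists passed camera in Dp16, a total of 5 with the region that rose to 17 without Dp16 replicate 4. Of 35 splits of the wild-type and Dp16 libraries into groups of 4, the real one included, 30 gave as many lists or more. Chance therefore stays open for this count. The 29 immediate early genes, which follow neuronal activity, fell with a median of -0.29 and 24 members negative (adjusted p = 2.48e-12, and adjusted p = 0.315 with an estimated correlation). Dusp1, a MAP kinase phosphatase, stood at 62.8 ± 8.14 CPM in wild-type and 37.7 ± 3.27 in Dp16, and 7 members, Dusp1, Btg2, Ier2, Junb, Fos, Nr4a1 and Egr2, fell when adjusted over the list alone against 0 over all genes. The 41 interferon-stimulated genes off chromosome 16 rose with a median of 0.34 and 34 members positive (adjusted p = 1.48e-06, and adjusted p = 0.315 with an estimated correlation). Of these, 1 rose when adjusted over the list alone, the lymphoid regulator Slfn2, from 3.78 ± 0.615 to 6.97 ± 0.477 CPM, and 0 over all genes. The interferon list score was 0.45 ± 0.173 in Dp16 against 0 ± 0.135 (two-sided exact permutation p = 0.0286, n = 4), while the immediate early score was -0.332 ± 0.314 against 0 ± 0.321 (p = 0.229 by the same test).

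The 21 inhibitory neuron markers rose by a median of 0.13, with 18 positive (adjusted p = 0.00874, and adjusted p = 0.0806 with an estimated correlation). Calb2, a calcium-binding protein of interneurons, stood at 12.8 ± 2.98 CPM in wild-type and 24.2 ± 2.92 in Dp16, a log2 change of 0.94, and Calb2 and the neuropeptide gene Npy rose when adjusted over the list alone, against 0 over all genes. The 13 mitochondrial genome transcripts rose by a median of 0.24, with 11 positive (adjusted p = 0.00139, and adjusted p = 0.535 with an estimated correlation). The two-sided exact permutation test of the scores gave p = 0.0286 for inhibitory neurons and 0.0857 for the mitochondrial genome. By the same test p was 0.0286 for choroid plexus and ependyma and for antigen presentation, both higher in Dp16, which did not pass camera. Without wild-type replicate 1 the inhibitory neuron call ended (adjusted p = 0.102), and without wild-type replicate 2 the mitochondrial genome call ended (adjusted p = 0.0718). Nonagouti no longer passed without wild-type replicate 1, Dp16 replicate 1 or Dp16 replicate 3 (adjusted p = 0.088, 0.0784 and 0.0941), and Jam2 and Morc3 passed in 1 of the 8 models that left out a library.

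Microglial lists did not pass camera in Dp16. Disease-associated microglia genes had a median of 0.03 and a mean of 0.19 (adjusted p = 0.0521), with Cd52 and Clec7a higher by 1.00 and 1.33 on the log2 scale when adjusted over the list alone. Homeostatic microglia (0.07, adjusted p = 0.391), general myeloid genes (0.12, 0.212), perivascular and blood-derived macrophages (0.26, 0.325), lymphocytes (0.02, 0.779), reactive astrocytes (0.08, 0.184) and astrocyte markers (0.08, 0.325) did not pass either. The other glial, neuronal, vessel and region lists that did not pass were myelinating oligodendrocytes (median -0.11, adjusted p = 0.065), oligodendrocyte precursors (0.04, 0.657), excitatory neurons (0.04, 0.35), endothelium (0.16, 0.388), mural cells and fibroblasts (-0.02, 0.826), choroid plexus and ependyma (0.48, 0.0521), blood (0.03, 0.368), striatum (-0.006, 0.468) and hippocampus and thalamus (-0.003, 0.246). Pathway lists that did not pass were complement (0.19, 0.36), antigen presentation (0.33, 0.0521), lysosome (-0.005, 0.79), cholesterol synthesis (0.09, 0.368), presynaptic and postsynaptic proteins (-0.007, 0.411), the unfolded protein response (-0.07, 0.184), heat shock (-0.03, 0.0977), oxidative stress (0.01, 0.508), oxidative phosphorylation (-0.07, 0.208), ribosomal proteins (-0.07, 0.132) and protocadherins (-0.07, 0.973). The 39 orthologs of human chromosome 21 genes that lie on mouse chromosomes 10 and 17, outside the Dp16 segment, had a median of 0.08 (adjusted p = 0.391). Median and mean had opposite signs for excitatory neurons, hippocampus and thalamus, lysosome and protocadherins, and the test's direction was opposite to a positive median for lymphocytes and the rest of chromosome 16 (adjusted p = 0.976).

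5xFAD against wild-type asks what the amyloid transgenes do in cortex with 2 copies of the segment. Microglial genes of the disease-associated state rose most. Clec7a, a pattern-recognition receptor, rose from 0.574 ± 0.341 to 36.3 ± 12.2 CPM (SD, n = 4; 61.6-fold), and Cst7, a cysteine protease inhibitor, rose from 0.412 ± 0.631 to 40.5 ± 17.4 CPM (84.6-fold). The lipid-sensing receptor Trem2 rose 3.00-fold, its adaptor Tyrobp 3.07-fold, the chemokine Ccl6 8.02-fold and the lysozyme Lyz2 3.78-fold. Gfap, the intermediate filament of reactive astrocytes, rose from 162 ± 7.81 to 596 ± 260.0 CPM (3.57-fold).

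In this comparison 30 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 27 higher and 3 lower. The balance depended on the setting, with 24 higher and 32 lower once the length trend was removed, 125 and 109 by DESeq2, and 100 and 135 with no filter on low counts. It was 3 higher and 0 lower among males, and 7 higher and 0 lower with only the 2 groups compared in the model. Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779) changed by 5.94 on the log2 scale (SE 0.34, adjusted p = 7.04e-08). Cst7 (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944) changed by 6.4 (SE 0.64, adjusted p = 0.000136), and Trem2 (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147) by 1.59 (SE 0.17, adjusted p = 0.000274). Tyrobp changed by 1.62 (SE 0.22, adjusted p = 0.00192), Gfap by 1.83 (SE 0.26, adjusted p = 0.00283) and the costimulatory molecule Cd86 by 1.59 (SE 0.20, adjusted p = 0.000693). Thy1 (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579) changed by 0.88 (SE 0.11, adjusted p = 0.000669). The region gene Samsn1, an adaptor of immune cells, rose by 1.72 (SE 0.30, adjusted p = 0.0205). Itgax, an integrin subunit, stood at 0.013 CPM in wild-type and 2.41 ± 1.99 in 5xFAD (adjusted p = 0.0298). When single libraries were left out, Clec7a, Cst7, Ccl6, Trem2, Tyrobp, Cd86, Gfap, Thy1 and Gjc1 passed in 8 of 8 models, Ctss in 7, Samsn1, Ctsd and mt-Nd6 in 3, and Itgax, C1qb and Rtkn in 1. The count of genes was 16 to 19 without wild-type replicate 3 or 4 or without 5xFAD replicate 1, 2 or 3. The genes that fell were the gap junction gene Gjc1, from 6.93 ± 3.03 to 1.38 ± 0.287 CPM (log2 -2.31, SE 0.32, adjusted p = 0.0024), Rtkn (-0.59, SE 0.11, adjusted p = 0.0333) and Gm26917 (-0.99, adjusted p = 0.0361), which was chosen after its values were seen.

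Of the 33 disease-associated microglia genes, 32 were positive, with a median of 0.68 and a mean of 1.49; 10 rose over all genes and 16 when adjusted over the list alone (camera adjusted p = 1.47e-42, and adjusted p = 0.00068 with an estimated correlation). Among males the median was 0.452 (adjusted p = 6.8e-12), and 0.309 with the length trend removed as well (adjusted p = 2.95e-11). The list score was 1.35 ± 0.317 against 0 ± 0.104 (two-sided exact permutation p = 0.0286, n = 4). Of the 24 general myeloid genes 22 were positive, with a median of 0.63; 5 rose over all genes and 12 when adjusted over the list alone (adjusted p = 1.12e-15, and adjusted p = 0.0385 with an estimated correlation). Among them, the Fc receptor genes Fcgr3 and Fcer1g rose by 1.16 and 1.2 and the protease gene Ctss by 0.96. The 22 homeostatic microglia genes rose by a median of 0.20 (adjusted p = 0.00444, and adjusted p = 0.452 with an estimated correlation). Among them P2ry12 and Gpr34 rose by 0.57 and 0.91 and Rhob fell by 0.38 when adjusted over the list alone. The homeostatic call ended without wild-type replicate 2, 5xFAD replicate 1 or 5xFAD replicate 2 (adjusted p = 0.0951, 0.102 and 0.067).

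Complement genes rose by a median of 0.42 (adjusted p = 0.000314, and adjusted p = 0.22 with an estimated correlation), with 2 of 19 past the threshold over all genes and 5 when adjusted over the list alone. C1qa, C1qb and C1qc, the subunits of the classical pathway's initiating complex, changed by 0.67, 0.77 and 0.74. Interferon-stimulated genes off chromosome 16 rose by a median of 0.64, with 35 of 41 positive (adjusted p = 9.91e-10, and adjusted p = 0.138 with an estimated correlation). The antiviral gene Ifi27l2a and the interferon regulatory factors Irf7 and Irf9 changed by 2.61, 1.35 and 0.76, and 13 members rose when adjusted over the list alone, against 0 over all genes. Lysosome genes rose by a median of 0.08 (adjusted p = 0.0038, and adjusted p = 0.452 with an estimated correlation). Of its 36 members, 3 rose over all genes and 9 when adjusted over the list alone, among them the protease genes Ctsd (0.83) and Ctss. The lysosome call ended without wild-type replicate 4, 5xFAD replicate 1 or 5xFAD replicate 2 (adjusted p = 0.0558, 0.0965 and 0.0651), and the homeostatic, complement and lysosome calls ended when the contrast was made among males (medians -0.166, 0.276 and -0.053, adjusted p = 0.509, 0.369 and 0.516).

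**Figure D2:**
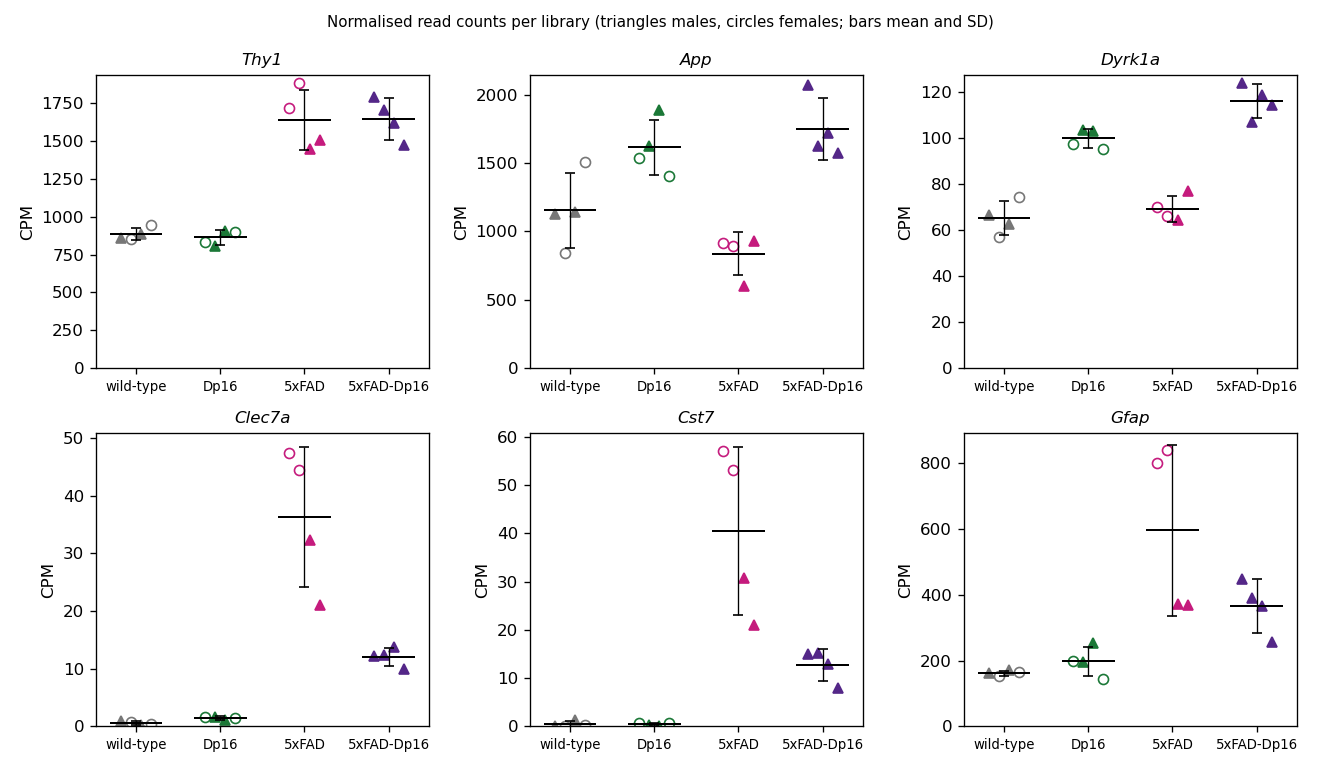
CPM (vertical axis, from 0) of Thy1, App, Dyrk1a, Clec7a, Cst7 and Gfap in the 4 genotypes (horizontal axis); triangles are males, circles females, and bars give the mean and SD of 4 animals. Clec7a and Cst7 are near 0 without the 5xFAD transgenes and higher in 5xFAD than in 5xFAD-Dp16, while App and Dyrk1a are higher in both groups with the duplication than in 5xFAD.

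Several lists fell in 5xFAD by camera while none of their members passed over all genes. Myelinating oligodendrocyte genes fell, with a median of -0.29, with 18 of 21 negative (adjusted p = 1.47e-07, and adjusted p = 0.206 with an estimated correlation), and 9 fell when adjusted over the list alone, among them the myelin genes Mog (-0.57) and Mag (-0.45). Immediate early genes fell, with a median of -0.51, with 28 of 29 negative (adjusted p = 2.63e-10, and adjusted p = 0.222 with an estimated correlation), and 5 fell when adjusted over the list alone: Dusp1, Ier2, Arc, Gadd45b and Junb. Endothelial genes fell, with a median of -0.65, with 17 of 18 negative (adjusted p = 2.39e-08, and adjusted p = 0.22 with an estimated correlation), of which the tight junction gene Cldn5 (-0.67) fell when adjusted over the list alone. Oligodendrocyte precursors (-0.36, adjusted p = 0.000991) and mural cells and fibroblasts (-0.61, adjusted p = 0.01) also fell, with adjusted p of 0.452 and 0.5 with an estimated correlation, and the mural call ended without wild-type replicate 2 or 5xFAD replicate 1 (adjusted p = 0.0951 and 0.0617).

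Mitochondrial genome transcripts rose by a median of 0.29 (adjusted p = 0.000182, and adjusted p = 0.222 with an estimated correlation), with mt-Nd6 past the threshold over all genes. Synaptic proteins fell by 0.19 (adjusted p = 0.00523), ribosomal proteins rose by 0.18 with 75 of 79 positive (adjusted p = 0.000109) and protocadherins fell by 0.32 (adjusted p = 0.0324). These 3 calls gave adjusted p of 0.621, 0.639 and 0.621 with an estimated correlation. Across genes, the log2 change correlated with gene length at rho = -0.145, and the median lengths were 5740.0 bases for synaptic, 1009 for ribosomal and 4727 for protocadherin genes. The 3 calls also ended without 5xFAD replicate 3 (adjusted p = 0.251, 0.743 and 0.458) or without wild-type replicate 4 (0.91, 0.804 and 0.953), and the protocadherin call without wild-type replicate 3 (0.145). Reactive astrocyte genes did not pass as a list (median 0.19, adjusted p = 0.165), with Gfap past the threshold over all genes and Gfap, Ggta1, Emp1 and Cxcl10 when adjusted over the list alone, of which Emp1 was lower. The region itself had a median of 0.07 (adjusted p = 0.154). The two-sided exact permutation test of the scores gave p = 0.0286 for general myeloid, myelinating oligodendrocyte and interferon-stimulated genes as well. The test also gave that p for antigen presentation and the rest of chromosome 16, which did not pass camera. It gave 0.0571 for mural cells and fibroblasts, 0.0857 for endothelium, 0.114 for immediate early genes, 0.143 for complement, 0.2 for the mitochondrial genome, 0.229 for oligodendrocyte precursors, 0.343 for homeostatic microglia, 0.429 for lysosome, 0.457 for ribosomal proteins, 0.543 for synaptic proteins and 0.743 for protocadherins.

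5xFAD-Dp16 against 5xFAD asks what the extra segment does where the amyloid transgenes are present. Region genes stood higher by a median of 0.51, or 1.43-fold, with 89 of 105 positive. Disease-associated microglia genes were lower in 5xFAD-Dp16, by a median of -0.35 (-0.319 to -0.611 when single libraries were left out, the latter without 5xFAD replicate 4), a call that ended with an estimated correlation (adjusted p = 0.478) and among males (median -0.225, adjusted p = 0.055). Clec7a stood at 12.03 ± 1.58 CPM against 36.3 ± 12.2 (SD, n = 4), Trem2 at 37.8 ± 3.48 against 78.0 ± 17.2, and Tyrobp at 49.0 ± 1.88 against 125 ± 32.0. Transcripts of ribosomal proteins and of oxidative phosphorylation were lower, by medians of -0.69 and -0.57, and those of synaptic proteins and oligodendrocyte precursors higher, by 0.47 and 0.71; these 4 calls ended with an estimated correlation (adjusted p = 0.657 for each), and the ribosomal median was -0.442 without 5xFAD replicate 3. The oligodendrocyte precursor list includes Olig1 and Olig2, which lie in the triplicated region. The 4 5xFAD-Dp16 animals were males and 2 of the 5xFAD animals were females.

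Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 4049 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0517; DESeq2 called 781 genes and limma voom 3841. The log2 change correlated with gene length at rho = 0.453 across genes. Once each library's length trend was removed, edgeR called 3 genes, each in the region: App (log2 0.723, adjusted p = 0.00402), Sod1 (0.689, 0.00402) and Synj1 (0.976, 0.0282). It called 2086 genes among males (29 in the region), 1928 among males with that removal (23 in the region), and 5020 with only the 2 groups compared. Each of these counts set 5xFAD-Dp16 against the 2 5xFAD males, whose rho of expression deviation with gene length was -0.462 and -0.239. In the model without these settings, Ifngr2, Dyrk1a, Ncam2 and Fcgr3 shared the smallest adjusted p, with log2 differences of 0.83, 0.72, 0.96 and -1.08. In the region, 39 genes were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.23e-14, and adjusted p = 6.44e-06 with an estimated correlation). App was 2.1-fold higher (log2 1.07, SE 0.20, adjusted p = 0.0795, and 0.000818 over the list alone). The App difference was 1.186 among males and 0.723 with the length trend removed. App stood low in 5xFAD replicate 3, at 603.7 CPM against 892.5 to 933.4 in the other 5xFAD libraries. Ifnar1 and Ifnar2 were higher by 0.78 and 1.00 (adjusted p = 0.0811 and 0.0795), and Il10rb, Rcan1, Sod1, Usp16 and Mx2 had values of 0.22, 0.53, 0.28, 0.20 and 0.24. The region score was 0.66 ± 0.033 against 0.13 ± 0.053 (two-sided exact permutation p = 0.0286, n = 4).

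The disease-associated microglia list fell by camera (adjusted p = 2.07e-05, and adjusted p = 0.478 with an estimated correlation), with 22 of 33 negative. When adjusted over the list alone 12 members fell and Timp2, a metalloproteinase inhibitor, rose, against 0 over all genes. Tyrobp, Ccl6 and Trem2 changed by -1.27, -1.59 and -0.95 (SE 0.23, 0.31 and 0.19), each with an adjusted p of 0.000736 over the list alone. Its score was 0.88 ± 0.095 in 5xFAD-Dp16 and 1.35 ± 0.317 in 5xFAD, a difference of -0.47 (two-sided exact permutation p = 0.0286, n = 4). Among males, 4 against 2, the score difference was -0.21 (two-sided exact permutation p = 0.0667, the smallest possible), and the list's adjusted p by camera was 0.055. Homeostatic microglia genes had a median of 0.02, a mean of -0.06 and a negative direction in the test (adjusted p = 0.308), with Gpr34, P2ry12 and Cst3 among those lower when adjusted over the list alone. General myeloid and lysosome genes had medians of -0.26 and -0.07 (adjusted p = 0.0821 and 0.308), with 4 and 7 members lower when adjusted over the list alone and 0 over all genes in each.

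**Figure D3:**
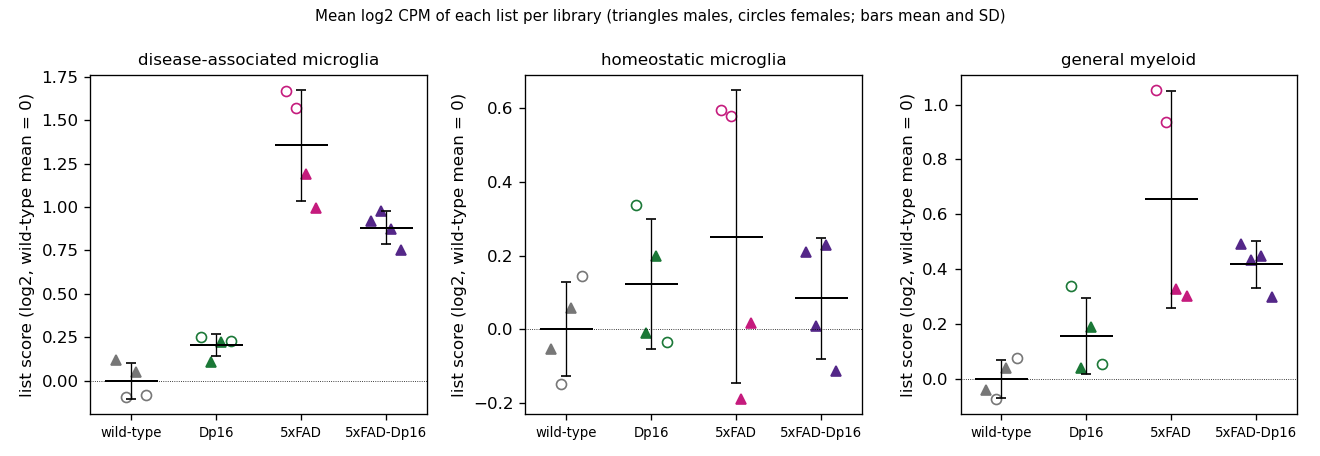
Score per library (log2, wild-type mean at 0, vertical axis) of the disease-associated microglia, homeostatic microglia and general myeloid lists in the 4 genotypes (horizontal axis); triangles are males, circles females, and bars give the mean and SD of 4 animals. The disease-associated score is 1.35 in 5xFAD, 0.88 in 5xFAD-Dp16 and 0.20 in Dp16, while the homeostatic score overlaps between genotypes.

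Ribosomal protein genes fell with 0 of 79 positive, and 74 fell when adjusted over the list alone (adjusted p = 1.82e-32, and adjusted p = 0.657 with an estimated correlation). Oxidative phosphorylation genes fell with 84 of 93 negative and 48 past the threshold when adjusted over the list alone (adjusted p = 1.34e-16, and adjusted p = 0.657 with an estimated correlation). Neither list had a member past the threshold over all genes; Rps19, Rpl31 and the complex I gene Ndufb9 had log2 differences of -0.88, -0.80 and -0.80. Synaptic proteins rose with 35 of 39 positive (adjusted p = 5.52e-06), excitatory neuron markers by 0.44 (0.00138), hippocampus and thalamus markers by 0.77 (0.000899), immediate early genes by 0.55 (0.000232), protocadherins by 0.69 (9.44e-05), oligodendrocyte precursors with Olig1, Olig2 and Sox10 past the threshold over the list alone (0.00142), and endothelium by 0.42 (0.0125). These 7 lists had adjusted p of 0.657 with an estimated correlation, apart from 0.478 for hippocampus and thalamus. The endothelium call ended without 5xFAD replicate 3 (adjusted p = 0.101). Olig1 and Olig2 lie in the triplicated region, so their rise cannot be told apart from an effect of their extra copy. The precursor list was not tested without them. The two-sided exact permutation test of the scores gave p = 0.0286 for ribosomal proteins, hippocampus and thalamus and synaptic proteins, 0.0571 for excitatory neurons and immediate early genes, 0.0857 for endothelium, 0.114 for oxidative phosphorylation, 0.143 for protocadherins and 0.229 for oligodendrocyte precursors. Median gene lengths were 983 bases for oxidative phosphorylation, 1009 for ribosomal proteins, 4359 for excitatory neurons, 4428 for hippocampus and thalamus, 4727 for protocadherins and 5740.0 for synaptic proteins.

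**Figure D4:**
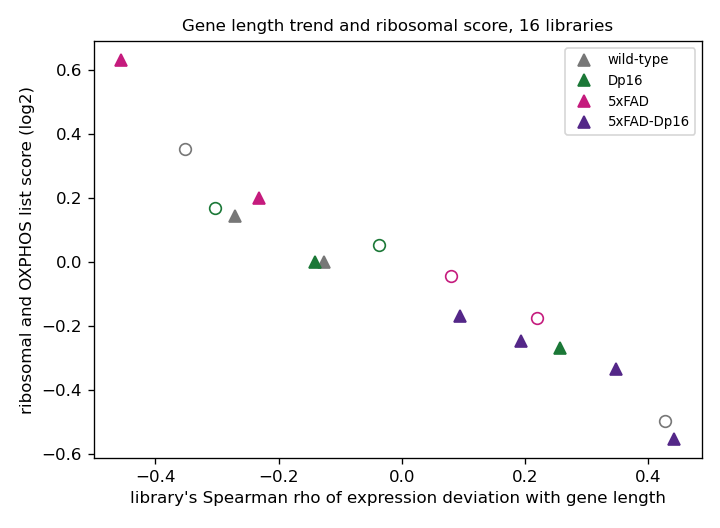
Mean score of the ribosomal protein and oxidative phosphorylation lists (log2, wild-type mean at 0, vertical axis) against the library's Spearman rho of expression deviation with gene length (horizontal axis) for 16 libraries; colours are genotypes, triangles males and circles females. Genes of both lists were left out of rho. The score falls as rho rises, and the 4 5xFAD-Dp16 libraries lie at rho of 0.094 to 0.442.

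5xFAD-Dp16 against Dp16 asks what the amyloid transgenes do where the segment is in 3 copies. Clec7a rose 9.82-fold, from 1.45 ± 0.299 to 12.03 ± 1.58 CPM (SD, n = 4), Cst7 rose 39.7-fold, from 0.440 ± 0.305 to 12.7 ± 3.39 CPM, and Thy1 rose 1.99-fold. These 3 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with log2 changes of 3.30 (SE 0.32, adjusted p = 0.00023), 5.31 (SE 0.69, adjusted p = 0.0037) and 0.99 (SE 0.12, adjusted p = 0.00143). Thy1 was a check of the labels, and its rise cannot be told apart from reads of any Thy1 sequence in the transgenes. Cst7 no longer passed without Dp16 replicate 2 (adjusted p = 0.0653). Disease-associated microglia genes rose by a median of 0.38 with 26 of 33 positive, 2 past the threshold over all genes and 5 when adjusted over the list alone (adjusted p = 2.95e-12, and adjusted p = 0.142 with an estimated correlation). The median of these genes was 0.241 among males, 0.234 with only the 2 groups compared, and 0.227 among males with the length trend removed. Their score was 0.88 ± 0.095 against 0.20 ± 0.063 (two-sided exact permutation p = 0.0286, n = 4). General myeloid genes rose by 0.34 (adjusted p = 2.37e-05, and adjusted p = 0.309 with an estimated correlation), with 0 members past the threshold over all genes or over the list alone.

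Immediate early genes rose by a median of 0.33 (adjusted p = 2.46e-05, and adjusted p = 0.448 with an estimated correlation), with 4 past the threshold when adjusted over the list alone, Fos, Nr4a1, Dusp1 and Egr2, and 0 over all genes. With the length trend removed and the contrast among males this median turned to -0.014 (adjusted p = 0.0365). Unfolded protein response genes fell by 0.18 (adjusted p = 0.00176, and 0.211 with an estimated correlation), and the 7 blood genes, among them the haemoglobin genes, fell by 0.71 (0.00132, and 0.309). Myelinating oligodendrocyte genes fell by 0.15 (0.00377, and 0.448) and endothelium fell by 0.22 (0.00395, and 0.474). Excitatory neurons rose by 0.32 (0.000288, and 0.406), hippocampus and thalamus by 0.37 (0.0154, and 0.406), synaptic proteins by 0.23 (2.14e-05, and 0.474) and protocadherins by 0.29 (0.00132, and 0.532). Oxidative phosphorylation fell by 0.36 (7.36e-20, and 0.43) and ribosomal proteins fell by 0.42 (2.89e-26, and 0.406), and the log2 change correlated with gene length at rho = 0.458 across genes. The lymphocyte list (4 of its members measured, 0.08, adjusted p = 0.00851, and 0.21 with an estimated correlation) rose with Thy1 among its members, and without Thy1 its adjusted p was 0.854; with no sex term its median turned to -0.107. The two-sided exact permutation test of the scores gave p = 0.0286 for the unfolded protein response, 0.0571 for general myeloid genes and ribosomal proteins, 0.0857 for oxidative phosphorylation and for hippocampus and thalamus, 0.114 for blood and excitatory neurons, 0.143 for myelinating oligodendrocytes, 0.171 for synaptic proteins and protocadherins, 0.229 for immediate early genes, 0.486 for endothelium and 0.714 for lymphocytes. Calls that ended without a single library were the oligodendrocyte and hippocampus lists without Dp16 replicate 2 (adjusted p = 0.097 and 0.126) and endothelium without Dp16 replicate 3 or 5xFAD-Dp16 replicate 4 (0.579 and 0.129).

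5xFAD-Dp16 against wild-type compares animals that carry the transgenes and the extra segment with animals that carry neither. Clec7a stood 24.7-fold higher, Cst7 36.3-fold and Thy1 1.94-fold. Dyrk1a rose from 65.1 ± 7.35 to 116 ± 7.19 CPM (SD, n = 4; log2 0.81, SE 0.12, adjusted p = 0.0132), the neural adhesion gene Ncam2 rose by 0.95 (SE 0.16, adjusted p = 0.0274) and Ttc3, an E3 ubiquitin ligase, by 0.66 (SE 0.11, adjusted p = 0.0363). Vat1l rose by 0.77 (SE 0.12, adjusted p = 0.0252), and nonagouti, at 2.48 ± 0.316 CPM with 38 to 51 reads per library, was at least 53-fold above the wild-type floor (adjusted p = 0.0252). These 8 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 6.51e-06, 0.003 and 0.00243 for Clec7a, Cst7 and Thy1. When single libraries were left out, Clec7a, Cst7 and Thy1 passed in 8 of 8 models, Dyrk1a in 3, nonagouti in 2, and Ncam2, Ttc3 and Vat1l in 1. The count was 21 without wild-type replicate 4 and 3 to 5 without any of the other 7 libraries. It was 0 with only the 2 groups compared in the model, 2 among males and 106 by DESeq2.

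Region genes had a median of 0.56 (1.48-fold), 98 of 105 positive, 3 past the threshold over all genes and 45 when adjusted over the list alone (adjusted p = 1.93e-07 with an estimated correlation). Disease-associated microglia genes rose by 0.45, with 2 past the threshold over all genes and 12 over the list alone (adjusted p = 4.56e-14, and adjusted p = 0.0521 with an estimated correlation). Their median was 0.35 among males, 0.283 with only the 2 groups compared, and 0.205 among males with the length trend removed. General myeloid genes rose by 0.45 (2e-06, and 0.242 with an estimated correlation), interferon-stimulated genes off chromosome 16 by 0.46 (1.26e-05, and 0.242) and complement by 0.28 (0.0204, and 0.407). Unfolded protein response genes fell by 0.21 (0.000125, and 0.0802), with the stress regulator Ddit3 and the folding factor Manf past the threshold over the list alone, at -0.62 and -0.59. Heat shock genes fell by 0.17 (0.0122, and 0.242) and myelinating oligodendrocyte genes fell by 0.28 (5.44e-05, and 0.252). Mitochondrial genome transcripts rose by 0.29 (0.00154, and 0.327).

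In the same comparison oxidative phosphorylation fell by 0.43 (3.47e-19, and 0.407 with an estimated correlation) and ribosomal proteins fell by 0.49 (7.57e-26, and 0.367). Hippocampus and thalamus rose by 0.45 (0.00223, and 0.242), excitatory neurons by 0.16 (0.028, and 0.623), synaptic proteins by 0.26 (0.00319, and 0.652) and protocadherins by 0.38 (0.00787, and 0.652). The log2 change correlated with gene length at rho = 0.432 across genes. Calls that ended without a single library were excitatory neurons (wild-type replicate 2 or 3, 5xFAD-Dp16 replicate 1 or 4; adjusted p = 0.126, 0.0879, 0.0936 and 0.0688), complement (wild-type replicate 4, 5xFAD-Dp16 replicate 2; 0.0593 and 0.0558), heat shock (wild-type replicate 3; 0.0528) and protocadherins (wild-type replicate 2, 5xFAD-Dp16 replicate 1; 0.173 and 0.0533). The two-sided exact permutation test of the scores gave p = 0.0286 for the region, disease-associated microglia, general myeloid, interferon-stimulated and myelinating oligodendrocyte genes. It gave 0.0571 for complement and heat shock, 0.0857 for the unfolded protein response and for hippocampus and thalamus, 0.171 for oxidative phosphorylation and ribosomal proteins, 0.229 for excitatory neurons and the mitochondrial genome, 0.343 for synaptic proteins and 0.371 for protocadherins.

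The interaction asks whether the extra segment has another effect where the amyloid transgenes are present. Disease-associated microglia genes had a negative interaction, with a median of -0.52 and 24 of 33 negative (camera adjusted p = 2.42e-07, and adjusted p = 0.467 with an estimated correlation). This median was -0.288 with the length trend removed (adjusted p = 9.5e-06), -0.31 by limma voom (0.0204) and -0.19 among males (0.0486), and fry did not pass (0.073). Clec7a had a value of -2.65 (SE 0.47), Trem2 -1.05 (SE 0.25) and Tyrobp -1.24 (SE 0.32), and 7 members were negative past the threshold over the list alone. Immediate early genes had a positive interaction, with a median of 0.88 and 28 of 29 positive (adjusted p = 2.93e-13, and adjusted p = 0.558 with an estimated correlation), and 8 members past the threshold over the list alone, among them Fos at 1.45 (SE 0.33) and Dusp1 at 1.02 (SE 0.20). Region genes had a median interaction of -0.05.

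Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes for the interaction, with 1591 at an unadjusted p under 0.05, a smallest adjusted p of 0.203 at Cd86 (-1.73), 21 genes by DESeq2 and 4 by limma voom. Across the 17019 genes, which are not independent replicates, the 5xFAD effects without and with Dp16 had r = -0.011 and rho = -0.159, with 41.3% of genes of the same sign and 3 genes higher in both against 0.00476 expected. Over the 9592 genes above 10 CPM these effects had r = -0.213 and rho = -0.349, with 36.4% of the same sign. The Dp16 effects without and with 5xFAD had r = 0.359 and rho = 0.101 over the region, with 80.0% of the same sign, and r = 0.094 and rho = 0.141 over other genes. By leaving out single libraries (jackknife), the SE of r was 0.205 for the 5xFAD effects. It was 0.365 for the Dp16 effects in the region and 0.301 for those outside it. The 5xFAD effects without and with Dp16 correlated with gene length at rho = -0.145 and 0.458. Their low agreement therefore cannot be told apart from a length bias between libraries. Over genes, the interaction correlated with gene length at rho = 0.385.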

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

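The tests of 1 library and of sex for the ribosomal pattern, and the tests of the microglial pattern, were chosen after the result was seen; the 2 tests of gene length for the ribosomal pattern were written before.

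Transcripts of ribosomal proteins and oxidative phosphorylation were lower in 5xFAD-Dp16 than in 5xFAD, with a joint score of -0.326 ± 0.166 against 0.154 ± 0.354 (SD, n = 4, two-sided exact permutation p = 0.0571). Both lists passed camera at the preset correlation and not with an estimated one (adjusted p = 0.657 for each). Within genotypes, this score followed the library's slope of expression on gene length over 16 libraries with r = -0.967 and rho = -0.962 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give; r = -0.943 without the 2 libraries farthest from the median), so a length bias between libraries may be part of the cause. After removal of the length trend the difference was -0.24 (-0.251 ± 0.084 against -0.011 ± 0.136, two-sided exact permutation p = 0.0286), which argues against length as the whole cause. The ribosomal median was -0.442 without 5xFAD replicate 3, which argues against that library as the whole cause. Among males it was -0.904, which cannot decide on the sex imbalance. The 2 5xFAD males were replicates 3 and 4, with length slopes of -0.455 and -0.231, against 0.219 and 0.08 in the females. The sex imbalance and an effect of the extra segment on these genes stay open and were not tested in another way.

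The disease-associated microglia list rose less in 5xFAD-Dp16 than in 5xFAD, with a score difference of -0.474 (two-sided exact permutation p = 0.0286, n = 4). Once the length trend was removed the median was -0.317, against -0.352 without removal, so it kept most of its size. The list still passed camera at the preset correlation (adjusted p = 0.000389). This pass cannot decide on a length bias as the whole cause, as up to 21 lists passed in other splits of these libraries. The call itself is less secure, as the adjusted p was 0.478 with an estimated correlation and no removal, and 2 of 35 splits of the libraries, this one included, reached a median as large in size (-0.371 in the other). The disease-associated minus the homeostatic score differed by -0.307 (0.797 ± 0.147 against 1.103 ± 0.187, two-sided exact permutation p = 0.0286), where fewer microglia of every kind predicted no separation. The nearest libraries lay at 0.967 in 5xFAD-Dp16 and 0.976 in 5xFAD. This cannot decide on fewer microglia, as the score was not corrected for gene length and the lists had median lengths of 1838 and 2940 bases. Sex cannot be told apart from the genotype here, because no 5xFAD-Dp16 animal was female: among males the score difference was -0.21 (two-sided exact permutation p = 0.0667, the smallest possible with 15 assignments). With the length trend removed and the contrast among males the median was -0.149 and the call ended (adjusted p = 0.23), against -0.352 (adjusted p = 2.07e-05) in all animals without removal; the median was smaller and only 2 5xFAD males carried the contrast. A lower microglial response with the extra segment, a length bias between libraries, fewer microglia of every kind, a stronger response in 5xFAD females and chance stay open.

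The Dp16 effect with the 5xFAD transgenes differed from that without them for 11 lists by camera's two-sided test of the interaction. Of 100 regroupings of the libraries, the real one included, 53 gave as many lists or more, so chance stays open for this count. The median interaction was -0.52 for disease-associated microglia (adjusted p = 2.42e-07), -0.24 for general myeloid genes (0.0127), -0.357 for interferon-stimulated genes off chromosome 16 (0.00074), -0.507 for oxidative phosphorylation (2.13e-11) and -0.611 for ribosomal proteins (1.18e-22). It was 0.607 for oligodendrocyte precursors (0.00913), 0.437 for excitatory neurons (0.000317), 0.587 for hippocampus and thalamus (0.0248), 0.884 for immediate early genes (2.93e-13), 0.372 for synaptic proteins (1.18e-06) and 0.671 for protocadherins (0.000317). With an estimated correlation the adjusted p was 0.467 for disease-associated microglia, 0.558 for immediate early genes and 0.58 for the other lists. Calls that ended without a single library were general myeloid genes (wild-type replicate 2, Dp16 replicate 3 or 5xFAD replicate 1; adjusted p = 0.186, 0.197 and 0.0913), oligodendrocyte precursors (5xFAD replicate 3; 0.0742), hippocampus and thalamus (wild-type replicate 4 or Dp16 replicate 2; 0.153 and 0.0786), interferon-stimulated genes (Dp16 replicate 3; 0.135) and protocadherins (wild-type replicate 4; 0.141). With the length trend removed the disease-associated median was -0.288 (adjusted p = 9.5e-06), among males -0.19 (0.0486), and with both -0.112, where the call ended (adjusted p = 0.188). Among males the general myeloid median was 0.038 (adjusted p = 0.843). As the 5xFAD-Dp16 animals were all males, sex and genotype are confounded in the contrast over all animals.

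The difference between females and males in 5xFAD, minus that in wild-type and Dp16, passed camera's two-sided test for 18 lists. Its median was 0.444 for disease-associated microglia (adjusted p = 5.06e-05), 0.498 for homeostatic microglia (9.29e-06), 0.577 for general myeloid genes (5.87e-06), 0.719 for complement (0.000678), 0.394 for lysosome (1.07e-06), 0.733 for antigen presentation (0.00633) and 0.323 for interferon-stimulated genes (0.0223). Astroglial, oligodendrocyte and neuronal lists gave 0.434 for reactive astrocytes (0.000104), 0.477 for astrocyte markers (3.37e-05), 0.775 for oligodendrocyte precursors (6.77e-05), 0.437 for excitatory neurons (0.0345), 0.532 for striatum (0.00189), 0.681 for immediate early genes (1.94e-06), 0.463 for synaptic proteins (0.00243) and 0.587 for protocadherins (0.000678). The remaining lists were oxidative phosphorylation at -0.72 (2.36e-18), the mitochondrial genome at 0.569 (0.00243) and ribosomal proteins at -0.651 (3.48e-16). With an estimated correlation the adjusted p was 0.0872 or higher for each list. For single genes edgeR called 0, with 2078 at an unadjusted p under 0.05, DESeq2 called 13, limma voom 0, and edgeR 1586 without wild-type replicate 4; the smallest adjusted p was 0.21 at the lysosomal glycoprotein gene Cd68 (1.61). These lists include the disease-associated list, the only microglial list that passed camera between 5xFAD and 5xFAD-Dp16, and each sex of 5xFAD had 2 animals. In 5xFAD the rho of expression deviation with gene length was 0.227 and 0.079 in the females, and -0.462 and -0.239 in the males. A sex difference in these lists therefore cannot be told apart from a length bias between libraries.

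Of 124 groups of 4 libraries, 8 held a value far from the other 3 by Dixon's test, while chance gives about 1 in 20. Itgax stood at 0.05258 CPM in wild-type replicate 4 and at 0.2025 in Dp16 replicate 3, with 0 in the other libraries of each group. App stood at 603.7 CPM in 5xFAD replicate 3 (892.5 to 933.4 in the others), and this library's median correlation with the rest was 0.938 (0.963 to 0.967). Nonagouti stood at 0.281 CPM in 5xFAD replicate 4 and at 0 in the others. Tyrobp stood at 77.34 CPM in 5xFAD replicate 4 (136.6 to 147.8 in the others) and Trem2 at 42.99 CPM in 5xFAD-Dp16 replicate 2 (35.84 to 36.28). The triplicated region score of 5xFAD replicate 2 was 0.054, against 0.154 to 0.169 in the others.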

How the results depend on the processing

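The alternatives chosen after the data were seen were both discordant libraries left out (wild-type replicate 2 and 5xFAD replicate 3), the length trend removed, that removal with the contrast among males, limma voom with library weights, and the lymphocyte list without Thy1. The median of the triplicated region kept its direction in each alternative, from 0.437 to 0.592 for Dp16 against wild-type and from 0.349 to 0.592 for 5xFAD-Dp16 against 5xFAD. With RLE factors the counts of genes were 3, 30, 0, 3, 8 and 0 for Dp16 against wild-type, 5xFAD against wild-type, 5xFAD-Dp16 against 5xFAD, Dp16 and wild-type, and the interaction, in that order below too, and 29 of the 30 were shared with TMM. The 1.5-fold changes called in simulations without a length trend ran from 4.5% to 20.9% among the 5 pairwise comparisons. With the length trend simulated and not removed the share was 1.5% for 5xFAD against wild-type. Whether depth, group size or the spread between animals limits these shares was not tested. The model with only the 2 groups compared was not run for the interaction, which needs all groups. The sample numbers did not pair the libraries (mean r -0.024 for the same number, 0.008 for others).

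DESeq2 called 35 genes (16 outside the region), 234, 781 (754 outside), 25, 106 and 21, and 13 for sex within 5xFAD; these include the 3, 30, 3 and 8 genes called by edgeR where edgeR called any. With no filter on low counts, which tests 29145 genes, edgeR called 43 (27 outside), 235, 2215 (2183 outside), 45, 292 and 346, and 398 for sex within 5xFAD, and kept 3, 29, 3 and 8 of those genes. Limma voom called 8 for Dp16 against wild-type (2 outside), 3841 for 5xFAD-Dp16 against 5xFAD (3796 outside), 38 against Dp16, 30 against wild-type and 4 for the interaction. The cause of these changes was not tested. In simulated data for 5xFAD against wild-type without a length trend, DESeq2 called 29 of 16470 unchanged genes. Limma voom called 4 such genes on the same data, and edgeR called 5 of 16483 on another simulation. DESeq2 also called more of the genes changed 2-fold, 68.7% against 53.7% by limma voom and 44.8% by edgeR.

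Among males, Dp16 against wild-type gave 0 genes (0 outside) and 8 lists, 5xFAD against wild-type 3 genes, 5xFAD-Dp16 against 5xFAD 2086 (2057 outside) and against wild-type 2. With only the 2 groups compared in the model, which leaves fewer libraries to estimate the spread, the counts were 0 (0 outside), 7, 5020 (4981 outside), 5 and 0, and the lymphocyte median in 5xFAD-Dp16 against Dp16 reversed to -0.004. For 5xFAD-Dp16, which holds males only, this setting again set its animals against the males of the other group. It is therefore not independent of the contrast among males there. With no sex term, 5xFAD-Dp16 against 5xFAD gave 16 genes (11 outside) and against wild-type 14, and the same lymphocyte median reversed to -0.107. With the sample number as a block, the counts were 0 for Dp16 against wild-type (0 outside, 8 lists), 20 and 0 for the next 2 comparisons, 2 against Dp16 and 3 against wild-type. The stricter filter gave 8 lists for Dp16 against wild-type. The cause was not tested.

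With the length trend removed, the counts were 1 for Dp16 against wild-type (11 lists), 56 for 5xFAD against wild-type and 3 for 5xFAD-Dp16 against 5xFAD, and Olig2 in Dp16 reversed to -0.015. That removal with the contrast among males gave 0 genes (0 outside) and 12 lists for Dp16 against wild-type, 9, 1928 (1905 outside) and 3 for 5xFAD-Dp16 against wild-type; Usp16 in Dp16 reversed to -0.037 and the immediate early median in 5xFAD-Dp16 against Dp16 to -0.014 (adjusted p = 0.0365). Without both discordant libraries, Dp16 against wild-type gave 1 gene and 12 lists, 5xFAD against wild-type 18 genes and 5xFAD-Dp16 against Dp16 5, and Olig2 in Dp16 reversed to -0.047. The cause was not tested. With camera at an estimated correlation, 1, 2, 1, 0, 1 and 0 lists passed; fry passed 2, 9, 2, 3, 6 and 0. The former uses the correlation estimated for each list in place of 0.01, and fry does not compare a list with other genes.

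When single libraries were left out, Dp16 against wild-type gave 0 to 2 genes (0 without wild-type replicate 1, Dp16 replicate 1 or Dp16 replicate 3), 0 to 1 outside the region, and 7 to 17 lists (9 to 17 without wild-type replicate 2 or 4 or Dp16 replicate 1, 2 or 4). 5xFAD against wild-type gave 16 to 26 genes (16 to 19 without wild-type replicate 3 or 4 or 5xFAD replicate 1, 2 or 3) and 12 to 17 lists. 5xFAD-Dp16 against 5xFAD gave 0 to 3 genes (3 without 5xFAD replicate 4), 0 to 3 outside, and 11 to 16 lists; against Dp16 2 to 4 genes and 13 to 17 lists; against wild-type 3 to 21 genes (21 without wild-type replicate 4) and 14 to 19 lists. The interaction gave 0 to 1 genes and 10 to 16 lists, and sex within 5xFAD 0 to 1586 genes (1586 without wild-type replicate 4). The region medians ran from 0.518 to 0.591 and from 0.522 to 0.577. The correlation of 5xFAD effects ran from -0.101 to 0.108, that of Dp16 effects in the region from 0.22 to 0.541 and outside it from -0.093 to 0.234. The lymphocyte median in 5xFAD-Dp16 against Dp16 ran from -0.153 to 0.522 (negative without Dp16 replicate 4, 5xFAD-Dp16 replicate 2 or 5xFAD-Dp16 replicate 4), Mx2 in Dp16 from -0.104 to 0.551 (negative without wild-type replicate 4 or Dp16 replicate 4), and Olig2 in Dp16 from -0.085 to 0.228 (negative without wild-type replicate 2, Dp16 replicate 1 or Dp16 replicate 3). Fewer libraries contribute to each of these.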

Other observations

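The tests of the microglial medians against other splits of the samples and of nonagouti as a fixed share of a neighbour's reads were chosen after the result was seen, as were the genes named in the next paragraph; the other tests of nonagouti and those of the counts and correlations were written before.

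A few transcripts stood apart in ways not described above. Eif2s3y, a Y-linked translation factor, stood at 46.5 and 43.2 CPM in the 2 5xFAD males, against 14.8 to 26.4 in the males of the other genotypes. The mitochondrial transcript mt-Nd6, the only protein-coding one on the light strand, stood at 124 to 142 CPM in 5xFAD and at 51.6 to 98.0 in the other 12 libraries. Gjc1 stood at 1.12 to 1.78 CPM in 5xFAD and at 2.26 to 11.2 elsewhere. The complex I transcript mt-Nd3 stood at 139 CPM in Dp16 replicate 2 and at 7.17 to 13.7 in the rest. Clec7a stood at 47.4 and 44.5 CPM in the 5xFAD females and at 32.3 and 21.0 in the males, and Gfap at 802 and 840.0 against 373 and 369.8.

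With the 8 libraries that carry the duplication set against the 8 that do not, 17 of 105 region genes were higher in each library with it, against 0.0082 expected by chance, and 0 were lower. Outside the region, nonagouti, Adamts2 and Otof were higher in each such library and Mcam, Acat3 and C230057M02Rik lower, that is, 3 in each direction where 1.3 are expected.

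Nonagouti had reads in the 8 libraries with the duplication, 0 in the wild-type libraries and 0 in 3 of the 4 5xFAD libraries. A fixed share of a neighbour's reads is argued against by the wild-type libraries: at the lowest share seen in a Dp16 library, any tested gene within 100 kb would give them at least 97.7 nonagouti reads together, where 0 were seen. Reads that run on from an overlapping gene in the duplication libraries alone cannot be told apart from transcription of nonagouti itself. The highest log2 change in Dp16 among these genes was 0.059 at Itch, and the overlapping gene Raly had -0.143 (SE 0.144), but the bound set in advance was wrong, since as many reads as nonagouti has would raise Raly by only 0.022. A segment of another strain's background around the gene cannot be told apart from an effect of the duplication: within 5 Mb, 3.3% of 151 genes had an unadjusted p under 0.05, against a median of 3.1% and a 95th percentile of 8% over 1000 random windows, and the labels name a strain only for the wild-type group. Read levels cannot show which allele was transcribed, or whether the reads came from this place on chromosome 2 at all. A regulatory effect of the extra segment on this gene stays open and was not tested.

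Other splits of the same libraries were fitted, 35 for each pair of groups and 100 for the interaction. A share of 1 of 35 is the smallest that 35 splits can give, and shares were not adjusted over the patterns tested. At that share chance is therefore called less likely here, not excluded. For the counts of genes, chance was less likely for 5xFAD-Dp16 against Dp16 (1 of 35 splits as large, 3 genes, highest other 0) and against wild-type (1 of 35, 8 genes, highest other 0). Another split gave a count as large for Dp16 against wild-type (2 of 35, 3 genes, highest other 764) and for 5xFAD against wild-type (2 of 35, 30 genes, highest other 815), so chance stays open there. With 0 genes called for 5xFAD-Dp16 against 5xFAD (35 of 35; highest other 0) and for the interaction (100 of 100; highest other 0), the splits decide nothing there. Splits with 764 and 815 genes point to a structure of the samples: in the latter, length rho ran from -0.128 to 0.435 on one side and from -0.462 to -0.239 on the other, and in the former from -0.36 to -0.041 and from -0.142 to 0.435. For the count outside the region in Dp16 against wild-type chance could not be excluded either (3 of 35; 1 gene, highest other 764), and for 5xFAD-Dp16 against 5xFAD, with 0 genes (35 of 35; highest other 0), the splits decide nothing.

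Chance was less likely for the region medians of Dp16 against wild-type (1 of 35, 0.551, highest other 0.4) and of 5xFAD-Dp16 against 5xFAD (1 of 35, 0.511, highest other -0.286). It was also less likely for the disease-associated microglia medians of 5xFAD against wild-type (1 of 35, 0.683, highest other 0.623) and 5xFAD-Dp16 against Dp16 (1 of 35, 0.382, highest other 0.263). It could not be excluded for that median in 5xFAD-Dp16 against 5xFAD (2 of 35, -0.352, highest other -0.371). For the counts of lists it could not be excluded in any comparison: Dp16 against wild-type (30 of 35; 5, highest other 18), 5xFAD against wild-type (4; 15, highest other 16), 5xFAD-Dp16 against 5xFAD (19; 11, highest other 21), against Dp16 (8; 14, highest other 23) and against wild-type (5; 15, highest other 20), and the interaction (53 of 100; 11, highest other 20). Nor could it be for the correlations of effects: 94 of 100 for 5xFAD effects (-0.011, highest other -0.757 in size), 21 for Dp16 effects in the region (0.359, highest other -0.761 in size) and 58 outside it (0.094, highest other -0.726 in size).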
